A study of Mus musculus with 14 samples.

How the data were processed

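RNA was measured in nuclei of hearts from ICR mice, enriched for PCM1-bearing cardiomyocyte nuclei. Per the labels' protocols and the series' design text, RNA was isolated with a column kit that yields DNA and RNA from 1 sample, and a commercial provider made polyA-selected, non-directional libraries, sequenced on a NovaSeq X Plus. The deposited values were whole-number read counts per Ensembl gene for 14 libraries, not normalized. STAR, limma and edgeR were named in the submitters' processing notes, with genome build GRCm38; their versions, the counting program, the annotation release and the strand setting were not given in the sources used here. Without strand, reads of a gene and of an overlapping gene on the other strand cannot be told apart, so counts of Mef2a, Ckm, Cacna1s and Uqcrc2 are uncertain. Library groups, replicate numbers and batches came from the labels, and a library is named by group and number, as Control 1.

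The table held 54446 genes. Symbols and coordinates were taken from GENCODE vM21, on the same build, by gene ID, and 54409 genes had a symbol; 102 symbols were carried by a second gene ID, and the first was used. No 2 columns were identical (0 pairs). Genes were kept by edgeR's filterByExpr with its default minimum count of 10 and total of 15, which left 17987. Analyses were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Counts were scaled by TMM factors. CPM values used these scaled library totals, and log2 CPM of a library used a prior count of 2.

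Before the data were examined, the comparisons, tests, gene lists, rule for named genes and most alternatives were fixed. The test was edgeR's quasi-likelihood F-test with robust dispersion, with group and batch as terms, over all 14 libraries, which share 1 estimate of the spread because only 2 libraries got both viruses. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. The biological coefficient of variation was 0.503. The 7 comparisons were each virus group against Control, the virus groups against each other, and the interaction, which is the change of both viruses against YAP5SA minus that of MEF2A against Control. All libraries with both viruses were in batch 1, so their comparison with other groups leans on the batch term.

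There were 37 lists of 675 genes, 660 of them tested. They cover metabolism, YAP and MEF2 targets, contractile genes, the cell cycle, stress, and markers of cell types, and are each named with a result in YAP5SA against Control. Lists were tested with limma's camera on voom values, with a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Camera compares a list with all other genes. With the correlation estimated from the data, 0 of 115 list calls held. With fry, which tests only whether members move on balance one way, 35 held. List calls therefore rest on the preset value.

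Named genes were Yap1 and Mef2a, and in each comparison the 5 called genes with the largest rise and the 5 with the largest fall. These needed a mean log2 CPM of at least 1, a gene symbol that is not a clone or provisional name, and every treated library on the same side of the mean of the reference libraries of its batch, or of all reference libraries where its batch held none. Largest is meant by this rule. From each list the rule took the 2 called members with the smallest p, or the 2 with the highest mean CPM where the text says that a list did not change, and members of short lists. The text gives a part of the list members and, in comparisons with both viruses or between viruses, the first 3 of each direction, shortened after their values were seen, often by genes whose call ended without 1 library, and 1 gene is not reported here. Fast skeletal muscle genes in the closing section were chosen after their values were seen.

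On simulated counts with 200 changed genes, drawn from the real means and library sizes over 17216 genes, edgeR recovered 13% of genes changed by 1 and 77% of those changed by 2 on the log2 scale for YAP5SA against Control (6 of 99 calls were false). For MEF2A against Control it recovered 40% and 80% (7 of 127 false), and for both viruses against Control 6% and 73% (3 of 82 false). Simulated 2-fold changes were mostly missed, with 200 genes changed. A shifted list and 0 of 36 others were called, but with genes left uncorrelated.

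Alternatives were RLE, upper-quartile or library-total scaling, no filter or a stricter one, DESeq2, limma-voom, no batch term, the replicate number in place of batch, only the groups compared, each batch alone, and removal of 443 mitochondrial, ribosomal and haemoglobin genes. A covariate for markers of other cell types and leaving out each library in turn were also tried. Chosen after seeing the data were leaving out Controls 1 and 2, leaving out these and YAP5SA 3, a term for sex, the sex term without Controls 1 and 2, and sample quality weights. Sex was called from Xist and Y-linked transcripts. Where a gene had 0 counts in a group, fold bounds used 3 counts over the group, which covers counting error only.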

Results

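The data were counts per gene from polyA-selected RNA of mouse heart nuclei enriched for PCM1, a protein found at the nuclei of cardiomyocytes. ICR mice, an outbred strain, had received adeno-associated virus AAV9 by intraperitoneal injection on postnatal day 7, and hearts were taken on postnatal day 12. The viruses expressed human MEF2A, a muscle transcription factor, or YAP5SA, a YAP variant that escapes inhibition by the Hippo pathway, from a cardiac troponin T promoter. The dose was 1E11 genome copies per virus. There were 5 Control libraries without virus, 4 MEF2A libraries, 3 YAP5SA libraries and 2 libraries that got both viruses, here called YAP5SA_MEF2A. Batch 1 held 8 libraries, 2 of each group, and batch 2 held 6 (3 Control, 2 MEF2A and 1 YAP5SA). Total counts ran from 16171068 to 24027622 per library. The labels do not state that each library is a separate animal, so p-values measure the spread between these libraries, which may be in part technical. Values after a gene are its log2 fold change ± SE and edgeR's adjusted p over all genes tested, and the median of a list is that of the log2 fold changes of its tested members, with camera's p. Every p of a list is adjusted. Control mice got no virus, so a difference from Control holds virus and transgene together.

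Mitochondrially encoded transcripts took 59.1% and 65.2% of counts in Controls 1 and 2, the only Controls of batch 1. This left 6607077 and 5949186 counts for all other genes, and 15274 and 15125 genes were detected, the fewest of the 14 libraries. YAP5SA 3 had 31.6%, and the other 11 libraries had 3.7% to 21.9%. Group means were 29.9% ± 29.8 (SD, n = 5) in Control, 16.7% ± 3.54 (SD, n = 4) in MEF2A, 13.9% ± 15.4 (SD, n = 3) in YAP5SA and 5.45% ± 0.524 (SD, n = 2) in YAP5SA_MEF2A. Correlations of log2 CPM across genes, which are not independent replicates, ran from 0.873 between Control libraries to 0.975 between the YAP5SA_MEF2A libraries. By Xist and Y-linked transcripts the YAP5SA libraries were all male and both YAP5SA_MEF2A libraries female, with 3 male and 2 female Controls and 1 male and 3 female MEF2A libraries.

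**Figure D1:**
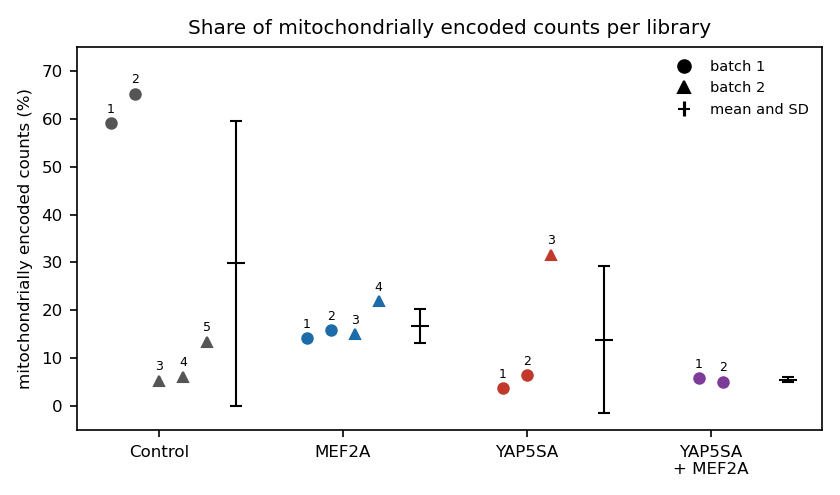
Percentage of counts from mitochondrially encoded genes (vertical axis) in each library, by group (horizontal axis), with replicate numbers beside the points; circles are batch 1, triangles batch 2, and bars show the group mean and SD. Controls 1 and 2 sit at 59.1% and 65.2%, above the other 12.

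Of the delivered factors, mouse Yap1 (ENSMUSG00000053110, chromosome 9, 7931999 to 8004596 on GRCm38) had 64 ± 10.1 CPM in Control (mean ± SD, n = 5), 73.3 ± 8.88 in MEF2A (n = 4), 55.7 ± 18.8 in YAP5SA (n = 3) and 74.8 ± 6.45 in YAP5SA_MEF2A (n = 2). Mef2a (ENSMUSG00000030557, chromosome 7, 67231163 to 67372858) had 556 ± 36.4 CPM in Control, 596 ± 25.5 in MEF2A, 393 ± 142 in YAP5SA and 523 ± 55 in YAP5SA_MEF2A. In edgeR's test the log2 fold change of Yap1 in YAP5SA was -0.30 ± 0.20 (SE, adjusted p = 0.389) and that of Mef2a in MEF2A was 0.07 ± 0.17 (adjusted p = 0.958). Mef2a was lower in YAP5SA than in MEF2A (-0.67 ± 0.21, adjusted p = 0.0365). Mef2a failed without MEF2A 1, 2, 3 or 4 or YAP5SA 1 or 3 (adjusted p = 0.0572 to 0.283). These values do not check the labels, since transgene reads need not be counted at the mouse genes. Mef2a overlaps Lysmd4 on the opposite strand, and the libraries carry no strand, so its counts are uncertain.

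YAP5SA against Control asks what active YAP changes in young cardiomyocytes, which the series title ties to metabolism and renewal. In the 3 YAP5SA libraries, targets of YAP and TAZ were higher than in the 5 Controls, by a median log2 fold change of 1.46, and genes of the actin cytoskeleton by 0.68. Sarcomere genes (median -0.68), calcium handling genes (-0.58) and TCA cycle genes (-0.41) were lower with TMM scaling. These medians were above 0 with library totals only, and the TCA cycle did not pass. Scel, which encodes the cell envelope protein sciellin, had the largest rise of the named genes (6.69 ± 0.62, adjusted p = 4.2e-05). It lies on chromosome 14, 103513342 to 103612797 (ENSMUSG00000022123) and went from 0.645 ± 0.825 CPM in Control (Control 2 highest, at 2.09) to 66.8 ± 36.7 in YAP5SA. Next were Cemip (6.39 ± 0.94, adjusted p = 0.00326) and Col4a3 (6.31 ± 0.69, adjusted p = 3.9e-04), which encode a hyaluronan-degrading protein and a basement membrane collagen. Vgll3, a TEAD cofactor, and Prss27, a serine protease, followed (6.15 ± 0.64, adjusted p = 5.1e-05 and 5.08 ± 0.87, adjusted p = 0.0040). The largest falls were in Bcl11b, a zinc finger transcription factor (-4.19 ± 0.86, adjusted p = 0.0056), and Phf24 (-3.36 ± 0.30, adjusted p = 2.9e-06). Rxfp1, a relaxin receptor, Gal3st2c and Rnft2 fell too (-3.20 ± 0.59, adjusted p = 0.00654, -3.10 ± 0.65, adjusted p = 0.00796 and -3.07 ± 0.50, adjusted p = 0.0022). In edgeR's test 1773 of 17987 genes changed, 1023 up and 750 down. With library totals as the only scaling, the median of all genes moved from 0.06 to 0.69 and 1703 genes were up and 33 down. Relative to that shifted median, each called list whose median changed sign with library totals, in any comparison, kept its sign under TMM except macrophage markers in both viruses against Control (0.14). The count was 1518 in batch 1, 2426 in batch 2 (1 YAP5SA library) and 2050 without Controls 1 and 2. It was 544 without YAP5SA 3, 692 without YAP5SA 1 and 2998 without YAP5SA 2. Without the 3 mitochondria-rich libraries (Control 1 and 2 and YAP5SA 3), chosen after seeing the data, 75 genes were called, the Controls then all being of batch 2 and YAP5SA of batch 1. Of the genes named here and in the next paragraphs only Scel, Col4a3, Vgll3, Phf24, Amotl2, Tgfb2, Wwc1, Col12a1 and Asph then passed (others adjusted p = 0.0876 to 0.823, with a log2 value over 1.5 times smaller for Cemip (3.20), Gal3st2c (-1.96) and Ttn (-0.61)). The falls of Bcl11b (-4.56), Rxfp1 (-3.24) and Rnft2 (-3.44) kept their size but not their call. Cemip failed without YAP5SA 3 (adjusted p = 0.0668). Gal3st2c failed without YAP5SA 1 (adjusted p = 0.0521).

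Targets of YAP and TAZ rose as a group (median 1.46, camera adjusted p = 1.4e-09, p = 0.121 with estimated correlation). Of 21 members, 12 rose, and 15 rose adjusted over the list alone. Amotl2, a scaffold that binds YAP, rose (3.19 ± 0.35, adjusted p = 6.3e-05), as did Tgfb2, a TGF-beta family growth factor (2.84 ± 0.29, adjusted p = 1.3e-05). The list of Hippo pathway and TEAD genes did not pass (median 0.33, camera adjusted p = 0.0537, p = 0.233 with estimated correlation). Among 18 members 4 rose, and 7 rose and 1 fell adjusted over the list alone. Wwc1, an upstream Hippo regulator, rose (4.10 ± 0.42, adjusted p = 2.4e-05). Actin cytoskeleton and focal adhesion genes rose (median 0.68, camera adjusted p = 6.1e-05, p = 0.384 with estimated correlation). Of the 25 members 11 rose, and 16 rose and 1 fell adjusted over the list alone. Extracellular matrix genes rose (median 0.62, camera adjusted p = 5.8e-05, p = 0.384 with estimated correlation). Of 24 members, 9 rose, and 11 rose adjusted over the list alone. The collagen gene Col12a1 (5.04 ± 0.42, adjusted p = 1.4e-05) was among them. Fibroblast markers did not pass (median 0.88, camera adjusted p = 0.0676, p = 0.568 with estimated correlation). Among 12 members 3 rose, and 6 rose and 1 fell adjusted over the list alone. Macrophage markers rose as well (median 1.76, camera adjusted p = 5.0e-05, p = 0.384 with estimated correlation). Of the 12 members 2 rose, and 5 rose adjusted over the list alone. Control 3 was low in them (mean log2 CPM -0.089, other Controls 2.27 to 2.82), and without it they stayed called. Matrix genes and macrophage markers failed without YAP5SA 3 (medians 0.08 and 0.24). In batch 1 the medians of these 2 lists were -0.05 (adjusted p = 0.731) and -0.18 (0.542).

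Sarcomere genes of the mature heart fell in YAP5SA (median -0.68, camera adjusted p = 5.0e-07, p = 0.17 with estimated correlation, median 0.01 and p = 0.00448 with library totals). Of 16 members, 6 fell, and 10 fell adjusted over the list alone. Nebl, nebulette of the Z-disc, and Ttn, titin, were examples (-1.47 ± 0.21, adjusted p = 3.2e-04 and -1.55 ± 0.28, adjusted p = 0.0020). Calcium handling and ion channel genes fell (median -0.58, camera adjusted p = 5.0e-05, p = 0.234 with estimated correlation, median 0.08 and p = 0.00108 with library totals). Among 26 members 5 fell, and 1 rose and 9 fell adjusted over the list alone. They included Asph, whose products include junctin (-1.18 ± 0.21, adjusted p = 0.00195). Muscle genes linked to MEF2 factors fell on balance (median -0.48, camera adjusted p = 0.00557, p = 0.138 with estimated correlation, median 0.22 and p = 0.113 with library totals). Of the 24 members 2 rose and 6 fell, and 3 rose and 8 fell adjusted over the list alone. Ckm, the creatine kinase of muscle, fell (-1.67 ± 0.25, adjusted p = 4.9e-04). Control 1 stood apart in Ckm (67.7 CPM) and Control 4 in Nebl (361).

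Genes of oxidative metabolism fell in YAP5SA with TMM scaling. With library totals only, medians of these 4 lists were above 0 and only fatty acid genes passed. TCA cycle and pyruvate entry genes fell (median -0.41, camera adjusted p = 6.2e-05, p = 0.17 with estimated correlation, median 0.24 and p = 0.152 with library totals). Of 20 members, 1 rose and 7 fell, also adjusted over the list alone. Mdh2, malate dehydrogenase, was an example (-0.89 ± 0.17, adjusted p = 0.00369). Genes of fatty acid uptake and oxidation fell (median -0.59, camera adjusted p = 5.1e-05, p = 0.384 with estimated correlation, median 0.05 and p = 0.0198 with library totals). Among 26 members 4 fell, and 5 fell adjusted over the list alone. Their batch 1 median was -0.21 (adjusted p = 0.128). Genes of respiratory complex I fell (median -0.45, camera adjusted p = 2.8e-04, p = 0.464 with estimated correlation, median 0.21 and p = 0.103 with library totals). Of the 36 members 7 fell, and 9 fell adjusted over the list alone. Complexes II to V fell (median -0.40, camera adjusted p = 4.0e-05, p = 0.435 with estimated correlation, median 0.23 and p = 0.125 with library totals). Of 43 members, 6 fell, and 7 fell adjusted over the list alone. Without Controls 1 and 2 the calls of both lists ended, at medians of 0.21 (adjusted p = 0.527) and 0.06 (0.566). Without YAP5SA 3 as well, the complexes passed, with -0.39 (adjusted p = 9.3e-05) and -0.34 (5.5e-05). The mitochondrially encoded genes had a median of -1.55 (camera adjusted p = 0.00224, adjusted p = 0.533 with estimated correlation). It turned to 1.20 (adjusted p = 0.0106) without Controls 1 and 2. Mitochondrially encoded genes failed without Control 1 or 2 or YAP5SA 1 or 2 (median -1.37 to -0.57). Glycolysis did not pass, and its test pointed down (median 0.10, camera adjusted p = 0.453, p = 0.729 with estimated correlation). Among 22 members 2 rose and 3 fell, and 3 rose and 3 fell adjusted over the list alone. The list of serine, one-carbon and nucleotide synthesis did not pass (median 0.19, camera adjusted p = 0.0952, p = 0.393 with estimated correlation). Of the 26 members 3 rose and 1 fell, and 5 rose and 1 fell adjusted over the list alone.

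The integrated stress response rose in YAP5SA (median 1.09, camera adjusted p = 0.0381, p = 0.393 with estimated correlation). Of 11 members, 4 rose and 1 fell, also adjusted over the list alone. Targets of p53 rose (median 0.74, camera adjusted p = 0.0256, p = 0.369 with estimated correlation). Among 15 members 5 rose and 1 fell, and 7 rose and 1 fell adjusted over the list alone. Cyclins, their kinases and inhibitors rose (median 0.59, camera adjusted p = 0.0381, p = 0.233 with estimated correlation). Of the 15 members 2 rose, and 4 rose adjusted over the list alone. Immediate early genes rose (median 0.55, camera adjusted p = 0.00993, p = 0.464 with estimated correlation). Of 12 members, 1 rose, and 2 rose adjusted over the list alone. Control 3 was low in them (mean log2 CPM 0.84, other Controls 2.59 to 3.19). Regulators of mitochondrial transcription fell (median -0.32, camera adjusted p = 0.0236, p = 0.233 with estimated correlation, median 0.41 and p = 0.184 with library totals). Among 15 members 3 fell, also adjusted over the list alone. Endothelial markers fell (median -0.74, camera adjusted p = 0.0019, p = 0.384 with estimated correlation). Of the 12 members 4 fell, and 5 fell adjusted over the list alone. Their median was -0.05 (adjusted p = 0.279) without Controls 1 and 2, when p53 targets (camera adjusted p = 0.0718) and cyclins (0.0909) did not pass either. Immediate early genes did not pass without the 3 mitochondria-rich libraries (camera adjusted p = 0.306). Ribosomal protein genes rose (median 0.28, camera adjusted p = 0.0209, p = 0.729 with estimated correlation). Of 36 members, 1 rose, also adjusted over the list alone. Genes of MHC class I and complement rose (median 0.20, camera adjusted p = 0.017, p = 0.568 with estimated correlation, median 0.95 and p = 0.0538 with library totals). Not 1 of 15 members passed (4 higher at unadjusted p under 0.05), nor adjusted over the list alone. Control 2 was high in them (mean log2 CPM 6.23, other Controls 2.30 to 3.02), and their median was 2.92 (adjusted p = 1.5e-08) without Controls 1 and 2. Batch 1 medians of these 2 lists were -0.73 (adjusted p = 9.2e-12) and -2.48 (0.0444). The stress response failed without Control 3 or 5 or YAP5SA 1 or 3 (median 1.02 to 1.18). The p53 targets and immediate early genes failed without Control 3 or YAP5SA 3 (medians 0.63 and 0.41 to 0.45). Cyclins failed without Control 3 or YAP5SA 2 or 3 (median 0.52 to 0.66). Mitochondrial regulators and MHC class I failed without YAP5SA 3 (medians -0.14 and -1.95). Ribosomal proteins failed without Control 3, 4 or 5 (median 0.17 to 0.22). Ribosomal proteins turned to the other direction without YAP5SA 3 (median -0.37, camera adjusted p = 0.00763).

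DNA replication genes did not pass against Control (median 0.14, camera adjusted p = 0.453, p = 0.809 with estimated correlation). None of 24 members passed (2 higher at unadjusted p under 0.05), nor adjusted over the list alone. Genes of mitosis and cytokinesis did not pass either (median 0.18, camera adjusted p = 0.262, p = 0.809 with estimated correlation). Of 26 members, 1 fell, also adjusted over the list alone. Interferon genes had a median of -1.03 with a test pointing up (camera adjusted p = 0.453), and of 1.33 (adjusted p = 3.3e-05) without Controls 1 and 2. Control 2 was high in them (mean log2 CPM 5.13, other Controls 0.55 to 1.30). In the remaining lists, camera's medians were -0.00075 (adjusted p = 0.728) for the pentose phosphate pathway, 0.81 (0.117) for fetal and stress genes of the heart, 0.30 (0.321) for NRF2 and antioxidant genes and -0.15 (0.453) for cardiac transcription factors. They were 0.03 (adjusted p = 0.619) for mural cell markers, 0.53 (0.497) for lymphocyte markers, -1.27 (0.177) for erythroid markers and -0.26 (0.523) for epicardial, Schwann and adipose markers. The last medians were 0.54 (adjusted p = 0.0829) for nuclear long non-coding RNAs and 0.72 (0.0829) for sex-linked genes.

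**Figure D2:**
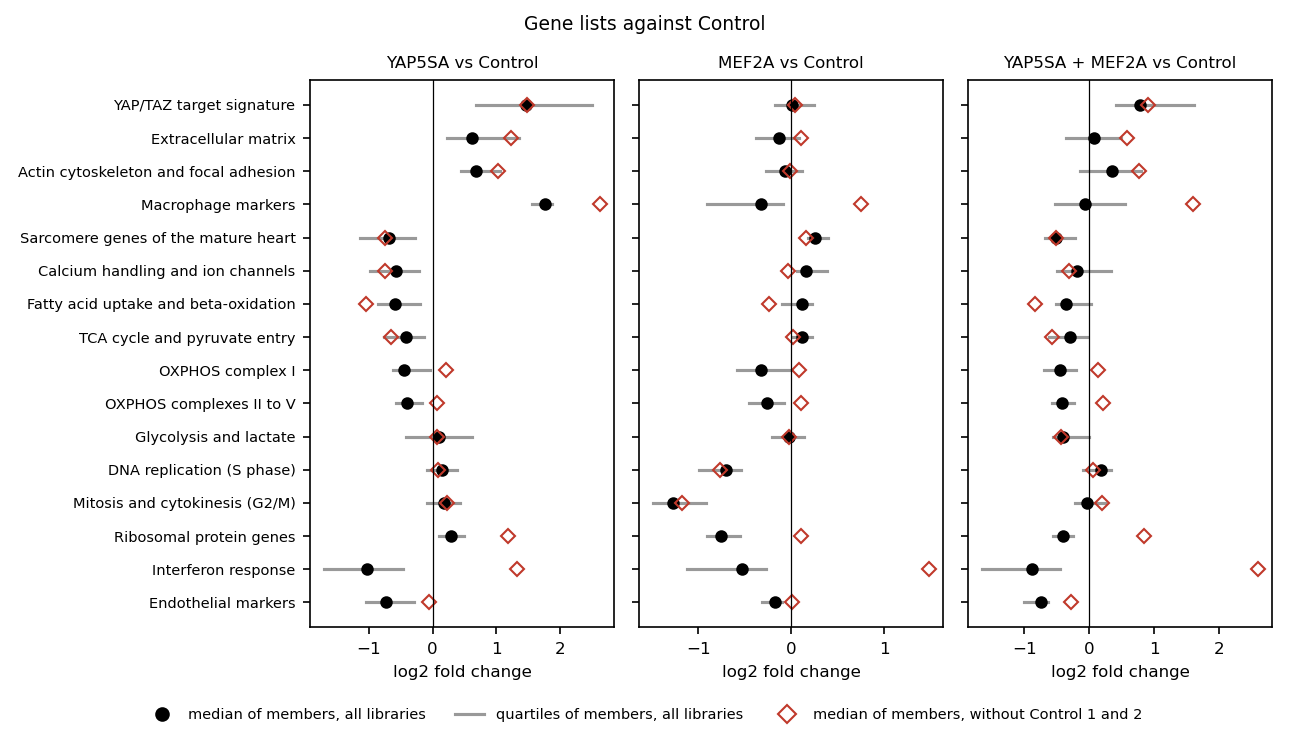
Median log2 fold change against Control of the tested members of 16 gene lists (vertical axis) in YAP5SA, MEF2A and both viruses, scaled by TMM; black points are medians and grey lines quartiles over all libraries, red diamonds medians without Controls 1 and 2. The YAP/TAZ target list has a median of 1.46 in YAP5SA, 0.01 in MEF2A and 0.78 with both viruses.

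Both viruses together were compared with Control in 2 libraries, both of batch 1, against 5. Sarcomere (-0.51), glycolysis (-0.40) and TCA cycle genes (-0.29) were lower with TMM scaling, and none of these 3 lists passed with library totals only. The largest rise was in Cacna1s, a calcium channel of skeletal muscle (6.38 ± 1.26, adjusted p = 0.0374). The collagen gene Col4a3 (5.41 ± 0.79, adjusted p = 0.00661) and Vgll3 (5.40 ± 0.73, adjusted p = 0.00108) followed. The largest falls were in Phf24 (-2.79 ± 0.35, adjusted p = 2.6e-04), the retinol binding protein gene Rbp7 (-2.75 ± 0.63, adjusted p = 0.0338) and Ttc39a (-2.42 ± 0.45, adjusted p = 0.00841). The YAP/TAZ target list rose (median 0.78, camera adjusted p = 6.0e-07, p = 0.178 with estimated correlation). Among 21 members 6 rose, and 9 rose and 1 fell adjusted over the list alone. Sarcomere genes fell (median -0.51, camera adjusted p = 1.1e-05, p = 0.178 with estimated correlation, median 0.29 and p = 0.193 with library totals). Of the 16 members 1 fell, also adjusted over the list alone. Nebl was the member that passed (-1.03 ± 0.25, adjusted p = 0.0473). In edgeR's test 244 of 17987 genes changed, 209 up and 35 down. With library totals as the only scaling, the median of all genes moved from 0.01 to 0.84 and 412 genes were up and 0 down. Called genes numbered 89 without YAP5SA_MEF2A 1, 90 without YAP5SA_MEF2A 2 and 142 without Control 1, 1395 in batch 1, 138 without Controls 1 and 2 and 43 without the 3 mitochondria-rich libraries. Of the genes named here only Phf24 then passed (others adjusted p = 0.0692 to 0.818, with a log2 value over 1.5 times smaller for Rbp7 (-0.79)). Cacna1s (5.07, adjusted p = 0.0793), Rbp7 (-1.28, adjusted p = 0.417) and Nebl (-1.25, adjusted p = 0.0843) failed without Controls 1 and 2. Cacna1s and Rbp7 failed without Control 1 or 2 or YAP5SA_MEF2A 1 or 2 (adjusted p = 0.057 to 0.261 and 0.0633 to 0.42). Col4a3 and Ttc39a failed without YAP5SA_MEF2A 1 or 2 (adjusted p = 0.0655 to 0.084 and 0.0745 to 0.188). Nebl failed without Control 1, 2, 4 or 5 or YAP5SA_MEF2A 1 or 2 (adjusted p = 0.0558 to 0.47).

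Metabolic lists fell with both viruses under TMM scaling, while with library totals only all 5 had medians above 0 and none passed. The TCA cycle list fell (median -0.29, camera adjusted p = 9.6e-05, p = 0.178 with estimated correlation, median 0.52 and p = 0.503 with library totals). Of 20 members, 1 rose and 1 fell, and 1 rose and 5 fell adjusted over the list alone. Glycolysis genes fell (median -0.40, camera adjusted p = 0.00445, p = 0.393 with estimated correlation, median 0.45 and p = 0.503 with library totals). No member of 22 passed (6 lower at unadjusted p under 0.05), and 3 fell adjusted over the list alone. Fatty acid genes fell (median -0.35, camera adjusted p = 0.0262, p = 0.65 with estimated correlation, median 0.40 and p = 0.82 with library totals). Of 26 members, none passed (4 lower at unadjusted p under 0.05), nor adjusted over the list alone. Complex I genes fell (median -0.45, camera adjusted p = 3.2e-05, p = 0.531 with estimated correlation, median 0.43 and p = 0.229 with library totals). Of 36 members, 1 fell, and 4 fell adjusted over the list alone. Complexes II to V fell with them (median -0.42, camera adjusted p = 4.2e-06, p = 0.531 with estimated correlation, median 0.48 and p = 0.472 with library totals). None of 43 members passed (12 lower at unadjusted p under 0.05), nor adjusted over the list alone. Without Controls 1 and 2 the medians of the complexes were 0.13 (adjusted p = 0.902) and 0.21 (0.747), and without YAP5SA 3 as well -0.15 (0.0354) and -0.08 (0.109). Cyclins did not pass without Controls 1 and 2 (camera adjusted p = 0.0512), nor Hippo genes without all 3 (0.0892). The median of the mitochondrially encoded genes went from -3.53 (camera adjusted p = 1.5e-06, adjusted p = 0.502 with estimated correlation) to 0.74 (adjusted p = 0.0766). Endothelial markers fell (median -0.73, camera adjusted p = 4.2e-06, p = 0.178 with estimated correlation, median 0.18 and p = 0.00452 with library totals), with a median of -0.28 (adjusted p = 0.0711) without these libraries. No member of 12 passed (7 lower at unadjusted p under 0.05), and 2 fell adjusted over the list alone. Actin and adhesion genes rose (median 0.35, camera adjusted p = 0.0127, p = 0.58 with estimated correlation). Of 25 members, 1 rose, and 3 rose adjusted over the list alone. Hippo pathway genes rose (median 0.10, camera adjusted p = 0.0332, p = 0.178 with estimated correlation). Among 18 members 1 rose, and 5 rose adjusted over the list alone. Cyclins and their regulators rose (median 0.44, camera adjusted p = 0.0235, p = 0.178 with estimated correlation, median 1.23 and p = 0.0672 with library totals). Of the 15 members 1 rose, and 2 rose adjusted over the list alone. MEF2-linked genes fell (median -0.14, camera adjusted p = 0.0194, p = 0.178 with estimated correlation, median 0.67 and p = 0.503 with library totals). Of 24 members, 1 fell, and 2 fell adjusted over the list alone. For macrophage markers the test pointed up, the median lay below 0 and the mean was 0.01. They passed (median -0.06, camera adjusted p = 0.0304, p = 0.65 with estimated correlation, median 0.98 and p = 0.372 with library totals). Of 12 members, none passed (0 at unadjusted p under 0.05), nor adjusted over the list alone. Batch 1 medians were -0.16 (adjusted p = 0.0603) for the TCA cycle, -0.48 (0.0603) for glycolysis and -0.07 (0.804) for fatty acid genes. They were 0.26 (adjusted p = 0.279) for actin genes, 0.20 (0.244) for Hippo genes and 0.64 (0.083) for cyclins. MEF2-linked genes had -0.13 (adjusted p = 0.083) and macrophage markers -0.75 (0.0874). Fatty acid genes failed without Control 3 or YAP5SA_MEF2A 2 (median -0.23 to -0.19). MEF2-linked genes failed without YAP5SA_MEF2A 1 (median -0.06). Macrophage markers failed without Control 3 (median -0.22).

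The comparisons of YAP5SA and of both viruses with Control use the same Controls. They shared 196 genes called higher and 34 called lower, against 11.9 and 1.46 for independent lists of their sizes. Simulated unchanged groups and Controls shared 0.05 higher genes on average in 20 runs. Log2 fold changes correlated at 0.743 across genes, which are not independent replicates, against 0.374 in the simulations. Their covariance was 1.65 against 0.401, which may miss traits of these Controls. With the Controls split between the comparisons in 2 ways, 120 and 131 higher and 13 and 20 lower genes were shared. The correlations were then 0.335 and 0.364. Split Controls were not simulated, so 0.374 is not the reference for these 2 values.

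**Figure D3:**
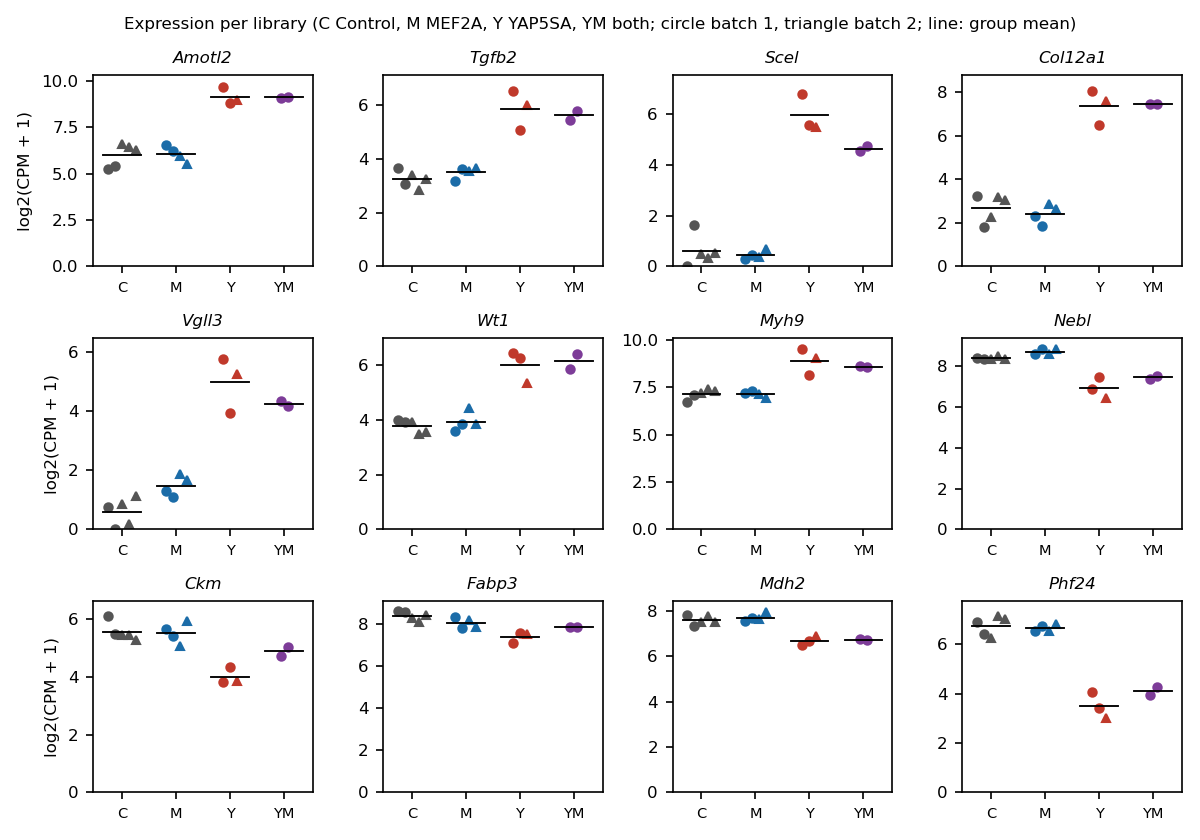
Expression of 12 genes as log2(CPM + 1) (vertical axis) in each library, for Control (C), MEF2A (M), YAP5SA (Y) and both viruses (YM); circles are batch 1, triangles batch 2, lines group means. Amotl2 averages 593 ± 198 CPM in YAP5SA and 555 ± 27.4 with both viruses, against 67.6 ± 26.7 in Control (mean ± SD).

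MEF2A against Control, in 4 libraries against 5, asks what MEF2A alone changes. Cell cycle genes were lower as groups in MEF2A, while few single genes passed. DNA replication and mitosis genes fell (medians -0.70 and -1.27, camera adjusted p = 9.2e-14 and 2.9e-13, p = 0.774 and 0.786 with estimated correlation). None of the 24 and 26 members passed. At unadjusted p under 0.05, 14 and 18 were lower, and 13 and 14 fell adjusted over the list alone. Without Controls 1 and 2 the medians were -0.76 (adjusted p = 6.4e-09) and -1.17 (2.9e-06). In batch 1 they were -0.63 (7.6e-05) and -1.55 (2.3e-14). Control 3 was below or among MEF2A in mean log2 CPM (mitosis 2.12, MEF2A 2.28 to 3.29, replication 3.07, MEF2A 2.70 to 3.14). All other Controls were above MEF2A. EdgeR called Slc38a3 (1.57 ± 0.25, adjusted p = 0.0496), Intu (1.03 ± 0.16, adjusted p = 0.0496) and Pde7a (0.96 ± 0.16, adjusted p = 0.0496). They encode an amino acid transporter, a planar cell polarity protein and a phosphodiesterase. They were the 3 genes called of 17987, with 1308 at an unadjusted p under 0.05 against 899 by chance. DESeq2 called 84 and limma-voom 0. With library totals only, edgeR called 0 and the median of all genes was 0.21. EdgeR's count was 0 without Control 1, 4 or 5 or MEF2A 2, 3 or 4, 1 without Control 2 or MEF2A 1 and 101 without Control 3, 482 in batch 1 and 22 in batch 2. Slc38a3 failed without Control 1, 4 or 5 or MEF2A 2, 3 or 4 (adjusted p = 0.13 to 0.212). Intu and Pde7a failed without Control 1, 2, 4 or 5 or MEF2A 1, 2, 3 or 4 (adjusted p = 0.0638 to 0.212 and 0.101 to 0.212). Intu (1.12, adjusted p = 0.089) and Pde7a (0.83, adjusted p = 0.292) failed without Controls 1 and 2.

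The other lists that passed in MEF2A did not pass without Controls 1 and 2. Ribosomal protein genes fell (median -0.75, camera adjusted p = 3.2e-14, p = 0.786 with estimated correlation). No member of 36 passed (16 lower at unadjusted p under 0.05), nor adjusted over the list alone. Without Controls 1 and 2 their median was 0.10 (adjusted p = 0.261). Complex I genes fell (median -0.32, camera adjusted p = 0.00298, p = 0.908 with estimated correlation). Of 36 members, none passed (7 lower at unadjusted p under 0.05), nor adjusted over the list alone. Complexes II to V fell (median -0.26, camera adjusted p = 6.1e-04, p = 0.908 with estimated correlation). Not 1 of 43 members passed (1 lower at unadjusted p under 0.05), nor adjusted over the list alone. Without these libraries their medians were 0.09 (adjusted p = 0.667) and 0.11 (0.298). Sarcomere genes rose (median 0.26, camera adjusted p = 0.00349, p = 0.786 with estimated correlation). None of 16 members passed (3 higher at unadjusted p under 0.05), nor adjusted over the list alone. Their median was 0.16 (adjusted p = 0.10) without these libraries, 0.27 (0.0179) without YAP5SA 3 as well and 0.17 (0.16) in batch 1. Calcium handling genes rose (median 0.16, camera adjusted p = 0.0129, p = 0.786 with estimated correlation). No member of 26 passed (4 higher at unadjusted p under 0.05), nor adjusted over the list alone. Erythroid markers fell (median -1.04, camera adjusted p = 0.0421, p = 0.786 with estimated correlation). Of 6 members, none passed (2 lower at unadjusted p under 0.05), and 2 fell adjusted over the list alone. Without these libraries the medians were -0.04 (adjusted p = 0.631) and -0.44 (0.611). Interferon genes had a median of -0.53 (camera adjusted p = 0.0503) and of 1.48 (adjusted p = 5.8e-17) without them. The YAP/TAZ target list did not pass (median 0.01, camera adjusted p = 0.928, p = 0.96 with estimated correlation). Not 1 of 21 members passed (2 higher at unadjusted p under 0.05), nor adjusted over the list alone. Complex I and complexes II to V failed without Control 1 or 2 or MEF2A 3 (medians -0.24 to -0.18 and -0.18 to -0.16). Sarcomere genes failed without Control 5 or MEF2A 4 (median 0.20 to 0.24). Calcium handling failed without Control 2 or 4 or MEF2A 4 (median 0.08 to 0.19). Erythroid markers failed without Control 1, 4 or 5 or MEF2A 1, 2 or 3 (median -1.13 to -0.30).

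YAP5SA against MEF2A, 3 libraries against 4, sets the transgenes against each other. YAP and TAZ targets were higher in YAP5SA, as were genes of mitosis and DNA replication. Sarcomere and calcium handling genes were lower. The largest rises were in Cemip (8.23 ± 1.14, adjusted p = 0.00192), Scel (7.30 ± 0.70, adjusted p = 5.5e-05) and Col4a3 (5.92 ± 0.72, adjusted p = 7.0e-04). The largest falls were in Gal3st2c (-3.76 ± 0.67, adjusted p = 0.00239), Rnft2 (-3.27 ± 0.51, adjusted p = 0.00121) and Kcnip2, a potassium channel subunit of the heart (-3.59 ± 0.83, adjusted p = 0.0184). MEF2A 4 stood apart in Gal3st2c (24.1 CPM). The YAP/TAZ target list rose (median 1.75, camera adjusted p = 3.6e-08, p = 0.0999 with estimated correlation). Of the 21 members 14 rose, and 15 rose adjusted over the list alone. Genes of DNA replication rose (median 0.90, camera adjusted p = 3.7e-05, p = 0.418 with estimated correlation). Of 24 members, 7 rose, and 11 rose adjusted over the list alone. Mitosis genes rose (median 1.44, camera adjusted p = 1.8e-05, p = 0.466 with estimated correlation). Among 26 members 13 rose, and 19 rose and 1 fell adjusted over the list alone. In edgeR's test 2679 of 17987 genes changed, 1398 up and 1281 down. With library totals as the only scaling, the median of all genes moved from 0.08 to 0.51 and 1526 genes were up and 79 down. Called genes numbered 841 without YAP5SA 3, 1213 without YAP5SA 1 and 1727 without MEF2A 4, 667 in batch 1, 2647 in batch 2 and 856 without the 3 mitochondria-rich libraries. Of these genes Cemip, Scel, Col4a3, Gal3st2c and Rnft2 then passed and Kcnip2 did not (adjusted p = 0.0635). Kcnip2 failed without YAP5SA 1 (adjusted p = 0.061).

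Sarcomere genes fell in YAP5SA relative to MEF2A (median -0.91, camera adjusted p = 3.6e-08, p = 0.159 with estimated correlation). Of the 16 members 11 fell, also adjusted over the list alone. Calcium handling genes fell (median -0.81, camera adjusted p = 2.4e-06, p = 0.169 with estimated correlation). Of 26 members, 13 fell, and 15 fell adjusted over the list alone. TCA cycle genes fell (median -0.53, camera adjusted p = 3.7e-05, p = 0.159 with estimated correlation). Among 20 members 1 rose and 9 fell, also adjusted over the list alone. Fatty acid genes fell (median -0.68, camera adjusted p = 3.7e-04, p = 0.429 with estimated correlation). Of the 26 members 8 fell, and 1 rose and 12 fell adjusted over the list alone. MEF2-linked genes fell (median -0.57, camera adjusted p = 9.3e-04, p = 0.0999 with estimated correlation). Of 24 members, 2 rose and 7 fell, and 3 rose and 11 fell adjusted over the list alone. Complexes II to V fell (median -0.18, camera adjusted p = 0.0265, p = 0.628 with estimated correlation, median 0.19 and p = 0.775 with library totals). Among 43 members 1 rose and 6 fell, also adjusted over the list alone. They did not pass without Controls 1 and 2 (camera adjusted p = 0.148). For complex I the test pointed down (median 0.05, camera adjusted p = 0.101). Of the 36 members 1 rose and 9 fell, and 2 rose and 9 fell adjusted over the list alone. For glycolysis it did too (median 0.14, camera adjusted p = 0.581). Of 22 members, 4 rose and 4 fell, and 6 rose and 7 fell adjusted over the list alone. Ribosomal proteins rose (median 1.06, camera adjusted p = 3.6e-08, p = 0.429 with estimated correlation). Among 36 members 10 rose, and 24 rose adjusted over the list alone. Matrix genes rose (median 0.74, camera adjusted p = 1.8e-05, p = 0.418 with estimated correlation). Of the 24 members 12 rose and 1 fell, and 14 rose and 1 fell adjusted over the list alone. Fibroblast markers rose with them (median 0.79, camera adjusted p = 0.0158, p = 0.429 with estimated correlation). Of 12 members, 5 rose, also adjusted over the list alone. Macrophage markers rose (median 2.45, camera adjusted p = 9.3e-04, p = 0.429 with estimated correlation). Among 12 members 3 rose, and 9 rose adjusted over the list alone. Endothelial markers fell (median -0.44, camera adjusted p = 0.0254, p = 0.429 with estimated correlation, median 0.01 and p = 0.108 with library totals). Of the 12 members 3 fell, and 4 fell adjusted over the list alone. Mitochondrially encoded genes fell as a list (median -0.43, camera adjusted p = 0.0158, p = 0.592 with estimated correlation), with no member called. Batch 1 medians of these 2 lists were -0.20 (adjusted p = 0.209) and -2.17 (5.9e-13). Complexes II to V and mitochondrially encoded genes failed without MEF2A 4 or YAP5SA 1 or 2 (medians -0.16 to -0.07 and 0.12 to 0.22). Fibroblast markers and macrophage markers failed without YAP5SA 3 (medians 0.38 and 0.69). Endothelial markers failed without MEF2A 3 or YAP5SA 2 (median -0.40).

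Both viruses against MEF2A alone, 2 libraries against 4, adds YAP5SA and a further virus dose to MEF2A. Targets of YAP and TAZ and mitosis genes were higher with both viruses, and sarcomere genes lower. The largest rises were in Cemip and Myh8, a perinatal myosin heavy chain of skeletal muscle (6.89 ± 1.15, adjusted p = 0.0168 and 5.95 ± 0.43, adjusted p = 6.6e-07). Scel rose next (5.65 ± 0.76, adjusted p = 0.00135). The largest falls were in Abcb4, a phospholipid transporter, and Cuzd1 (-3.33 ± 0.62, adjusted p = 0.0099 and -3.16 ± 0.80, adjusted p = 0.044). Atp2b2, a calcium pump, fell too (-3.13 ± 0.63, adjusted p = 0.0129). The YAP/TAZ target list rose (median 1.19, camera adjusted p = 8.7e-07, p = 0.0912 with estimated correlation). Of 21 members, 6 rose, and 11 rose adjusted over the list alone. Genes of DNA replication rose (median 0.81, camera adjusted p = 1.7e-05, p = 0.434 with estimated correlation). No member of 24 passed (12 higher at unadjusted p under 0.05), and 8 rose adjusted over the list alone. Mitosis genes rose (median 1.17, camera adjusted p = 1.2e-04, p = 0.59 with estimated correlation). Of 26 members, none passed (14 higher and 1 lower at unadjusted p under 0.05), and 6 rose adjusted over the list alone. Sarcomere genes fell (median -0.78, camera adjusted p = 1.6e-07, p = 0.0912 with estimated correlation). Of 16 members, 2 fell, and 8 fell adjusted over the list alone. TCA cycle genes fell (median -0.41, camera adjusted p = 1.9e-05, p = 0.0912 with estimated correlation, median 0.22 and p = 0.069 with library totals). Among 20 members 1 rose and 3 fell, and 1 rose and 7 fell adjusted over the list alone. Endothelial markers (median -0.76, camera adjusted p = 4.1e-04, p = 0.376 with estimated correlation), mural cell markers (median -0.51, camera adjusted p = 0.0166, p = 0.376 with estimated correlation, median 0.12 and p = 0.142 with library totals) and mitochondrially encoded genes (median -2.58, camera adjusted p = 3.3e-05, p = 0.477 with estimated correlation) fell as lists, with no member called. Their batch 1 medians were -0.32 (adjusted p = 0.014), -0.28 (0.112) and -1.94 (2.6e-13). In edgeR's test 417 of 17987 genes changed, 290 up and 127 down. With library totals as the only scaling, the median of all genes moved from 0.05 to 0.67 and 427 genes were up and 3 down. Called genes numbered 90 without YAP5SA_MEF2A 1, 103 without YAP5SA_MEF2A 2, 170 without MEF2A 2, 245 without MEF2A 1, 252 without MEF2A 3 and 267 without MEF2A 4. In batch 1 the count was 304, and 644 without Controls 1 and 2. Mural markers failed without YAP5SA_MEF2A 2 (median -0.40). MEF2A 1 stood apart in Abcb4 (22.6 CPM) and Atp2b2 (2.89). Cemip failed without MEF2A 1 or YAP5SA_MEF2A 1 or 2 (adjusted p = 0.0612 to 0.118). Abcb4 failed without YAP5SA_MEF2A 1 or 2 (adjusted p = 0.0751 to 0.195). Cuzd1 failed without MEF2A 1, 2, 3 or 4 or YAP5SA_MEF2A 1 or 2 (adjusted p = 0.064 to 0.525). Atp2b2 failed without MEF2A 2 or YAP5SA_MEF2A 1 or 2 (adjusted p = 0.0642 to 0.269). Cuzd1 (-3.06, adjusted p = 0.0578) failed without Controls 1 and 2 too. Myh8 is close in sequence to its neighbour genes, and Cuzd1 overlaps Fgfr2, so their counts are uncertain.

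Both viruses against YAP5SA alone, 2 libraries against 3, adds MEF2A and a virus dose. The interaction asks if their effect differs with YAP5SA present. As groups, calcium handling and sarcomere genes were higher with both viruses, and matrix, macrophage and mitosis genes lower. EdgeR called 0 single genes, with 516 at an unadjusted p under 0.05 against 899 by chance, while DESeq2 called 18 and limma-voom 1. For the interaction edgeR called 0, with 441 at an unadjusted p under 0.05, DESeq2 22 and limma-voom 0. EdgeR's counts were 227 without YAP5SA 2 for both viruses against YAP5SA and 11 without YAP5SA 2 for the interaction. They were 6 and 1 in batch 1. With library totals only the median of all genes was 0.19. Calcium handling genes rose (median 0.40, camera adjusted p = 1.0e-06, p = 0.426 with estimated correlation). Sarcomere genes rose (median 0.35, camera adjusted p = 0.012, p = 0.426 with estimated correlation). Matrix genes fell (median -0.61, camera adjusted p = 1.5e-08, p = 0.426 with estimated correlation). Macrophage markers fell (median -1.77, camera adjusted p = 0.00193, p = 0.426 with estimated correlation). These lists had no member of 26, 16, 24 and 12 passing, nor adjusted over the list alone. At unadjusted p under 0.05 were 0, 1 higher, 4 lower and 1 lower. Fibroblast (median -0.41, camera adjusted p = 0.00244, p = 0.426 with estimated correlation) and mural cell markers (median -0.32, camera adjusted p = 0.0418, p = 0.426 with estimated correlation, median -0.06 and p = 0.139 with library totals) fell as lists, with no member called. Targets of YAP and TAZ fell (median -0.45, camera adjusted p = 0.00334, p = 0.426 with estimated correlation). No member of 21 passed (5 lower at unadjusted p under 0.05), nor adjusted over the list alone. Ribosomal protein genes fell (median -0.68, camera adjusted p = 6.4e-11, p = 0.426 with estimated correlation). Of 36 members, none passed (3 lower at unadjusted p under 0.05), nor adjusted over the list alone. Mitosis genes fell (median -0.19, camera adjusted p = 0.0418, p = 0.747 with estimated correlation, median 0.01 and p = 0.0489 with library totals). Not 1 of 26 members passed (0 at unadjusted p under 0.05), nor adjusted over the list alone. Mitochondrially encoded genes fell (median -2.10, camera adjusted p = 0.0163, p = 0.628 with estimated correlation), with no member called. In batch 1 fibroblast markers had -0.09 (adjusted p = 0.128) and mitochondrially encoded genes 0.20 (0.0283). Sex and group coincide here. With a term for sex, informed by the other groups, medians were 0.34 (adjusted p = 8.5e-06) for calcium handling, 0.52 (8.5e-06) for sarcomere genes and -0.53 (3.3e-04) for matrix genes. They were -1.33 (adjusted p = 0.00316) for macrophage markers, -0.64 (0.156) for YAP and TAZ targets, -0.93 (3.4e-15) for mitosis and -0.02 (0.84) for ribosomal proteins. Fibroblast (adjusted p = 0.156), mural (0.976) and mitochondrially encoded lists (0.315) did not pass. Without Controls 1 and 2 as well, fibroblast markers (camera adjusted p = 0.00656) and ribosomal proteins (4.2e-05) were called lower. Sarcomere genes failed without YAP5SA_MEF2A 2 (median 0.28). Macrophage markers and fibroblast markers failed without YAP5SA 3 (medians -0.36 and -0.10). YAP and TAZ targets failed without YAP5SA 1 (median -0.02). Mural markers failed without YAP5SA 2 or 3 or YAP5SA_MEF2A 2 (median -0.32 to -0.13). Mitosis failed without YAP5SA 1, 2 or 3 or YAP5SA_MEF2A 2 (median -0.26 to -0.02). Mitochondrially encoded genes failed without YAP5SA 3 or YAP5SA_MEF2A 2 (median -1.95 to 0.20).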

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

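The tests of the respiratory chain lists and of the lists kept with a sex term, the sex terms of the interaction, and how the sign of the sex coefficient is read, were chosen only after the result was seen.

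Of 56 splits of the YAP5SA and Control libraries into groups of these sizes, only the real one called 1773 genes (highest other 671). For YAP5SA against MEF2A only the real of 35 splits called 2679 (highest other 72). The shares, 0.018 and 0.029, are the lowest possible, so chance is unlikely, not excluded. For MEF2A against Control 7 of 100 drawn splits called as many as the real 3, and chance cannot be excluded. The highest other called 180 and set Control 3 with the MEF2A libraries against the remaining Controls, which points to a structure of the samples.

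Respiratory chain genes were lower in YAP5SA than in Control. Without Controls 1 and 2, with over 50% mitochondrially encoded counts, the 79 nuclear-encoded members had a median log2 fold change of 0.095 in YAP5SA. Its 95% bootstrap interval, -0.104 to 0.242, just passes the bound of -0.1 set for this. Bootstrap intervals resample genes and miss the spread between libraries. Without YAP5SA 3 as well, complex I and the other complexes stayed called (medians -0.39 and -0.34, camera adjusted p = 9.3e-05 and 5.5e-05). These Controls stay open as a source. Against MEF2A, which has no such library, the median was -0.105. Its interval, -0.237 to 0.0974, spans the bound of -0.2 set for an effect of YAP5SA on the group. A fall from YAP5SA and a difference from these Controls cannot be told apart. The outcome turns on YAP5SA 3, and these are the only Controls of batch 1.

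Of lists that differed between both viruses and YAP5SA alone, 17 were called, the sex-linked list left out, while sex separates these groups completely. With a term for sex, from Control and MEF2A libraries, 5 of 17 stayed called in the same direction. For calcium handling, matrix and macrophage genes this argues against sex alone. Sarcomere and mitosis genes, also kept, had a male minus female coefficient with the sign of their change. All 12 lists that lost the call had the opposite sign. With 1 sex in each group such signs keep or end calls, so both decide nothing. Of the 12, fatty acid genes (camera adjusted p = 8.6e-04), cardiac factors (0.0243), fibroblast markers (0.00656) and ribosomal proteins (4.2e-05) passed again in the same direction with the sex term and without Controls 1 and 2, and medians of YAP and TAZ targets (-0.64, from -0.45), cardiac factors (0.35, from 0.25) and glycolysis (-0.37, from -0.39) were about as large with the sex term, so sex, virus dose and MEF2A cannot be told apart there. An effect of MEF2A or dose stays open for the 5 lists kept, but none held with estimated correlation, and without 1 library calls of sarcomere, macrophage and mitosis genes ended (without YAP5SA 1, 2 or 3 or YAP5SA_MEF2A 2 for mitosis, camera adjusted p = 0.056 to 0.458).

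For 13 lists the change with MEF2A differed by whether YAP5SA was present. With camera's adjusted p in parentheses, medians of the interaction were 0.29 (0.0466) for complex I, 0.21 (0.027) for complexes II to V, 0.23 (0.0111) for fatty acid genes and -0.38 (0.0296) for glycolysis. They were 0.60 (9.3e-07) for DNA replication, 0.96 (1.2e-04) for mitosis, -0.24 (0.0296) for YAP and TAZ targets and 0.14 (0.0296) for calcium handling. Matrix genes had -0.36 (8.1e-04), cardiac transcription factors 0.31 (0.041) and mural cell markers -0.48 (0.027). Macrophage markers had -1.14 (8.1e-04) and lymphocyte markers -1.37 (0.042). No list held with estimated correlation, and sex and dose are part of this contrast. With library totals only fatty acid genes (0.055), calcium handling (0.0564), cardiac factors (0.311) and mural markers (0.0564) did not pass. The loss of a call without a library follows, with the median then. Complex I lost it without Control 1, 2 or 5, MEF2A 1, 2 or 3, YAP5SA 1 or 2 or YAP5SA_MEF2A 1 (0.08 to 0.30). The other complexes lost it without Control 1 or 2, MEF2A 1, 2 or 3, YAP5SA 1 or 2 or YAP5SA_MEF2A 1 (0.08 to 0.20). Fatty acid genes lost it without Control 3, MEF2A 2 or 4, YAP5SA 3 or YAP5SA_MEF2A 1 (-0.06 to 0.14). Glycolysis lost it without Control 3 or 5, MEF2A 1 or 4, YAP5SA 1 or YAP5SA_MEF2A 1 (-0.43 to -0.13). YAP and TAZ targets lost it without Control 3 or 4, MEF2A 1, YAP5SA 1 or 3 or YAP5SA_MEF2A 1 (-0.38 to -0.08). Calcium handling lost it without Control 3 or 5, MEF2A 1 or 3, YAP5SA 1 or 3 or YAP5SA_MEF2A 2 (0.04 to 0.21). Matrix genes lost it without YAP5SA 3 (-0.16). Cardiac factors lost it without Control 3, 4 or 5, MEF2A 1, 3 or 4, YAP5SA 2 or 3 or YAP5SA_MEF2A 2 (-0.09 to 0.39). Mural markers lost it without Control 3 or 4, MEF2A 4, YAP5SA 2 or 3 or YAP5SA_MEF2A 2 (-0.65 to -0.31). Macrophage markers lost it without Control 3 or YAP5SA 3 (-0.74 to -0.28). Lymphocyte markers lost it without Control 1, 3, 4 or 5, MEF2A 1, 2 or 3, YAP5SA 1 or 3 or YAP5SA_MEF2A 1 or 2 (-1.37 to -0.90). DNA replication and mitosis kept the call without any single library, but with a sex term (median and adjusted p in parentheses) DNA replication lost it (0.35, 0.0641) and the test of mitosis turned (0.56, 0.874). With the sex term and without Controls 1 and 2, DNA replication did not pass (0.0082, 0.886) and mitosis was called lower (-0.56, 9.2e-04). In batch 1 alone the tests of fatty acid genes (-0.45, 0.401), matrix genes (0.12, 0.139), macrophage markers (0.50, 0.139) and mural markers (-0.20, 0.736) pointed the other way.

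A library stood apart from the rest of its group in 20 of 230 values, where chance alone picks about 1 in 20 groups. Control 2 was high in mean log2 CPM of interferon genes (5.13, others 0.55 to 1.30) and of MHC class I and complement genes (6.23, others 2.30 to 3.02). Control 3 was low in macrophage markers (-0.089, others 2.27 to 2.82) and immediate early genes (0.84, others 2.59 to 3.19), and Control 5 high in epicardial, Schwann and adipose markers (2.56, others 1.58 to 1.72). The only male of its group, MEF2A 4, had 632 CPM of Y-linked transcripts and was high in sex-linked genes (6.06, others -0.83 to -0.13). In CPM, library 1 of MEF2A was apart in Abcb4 (22.6), Atp2b2 (2.89), Eci1 (187), Myh1 (0.381) and Cdh15 (0.0544), and library 4 in Gal3st2c (24.1). Among Controls these were Ckm in library 1 (67.7), Scel (2.09) and Uqcrc2 (49.8) in library 2, and Ube2c in library 3 (0.612). The remaining were Nebl (361) and Mybph (0.538) in library 4 and Atp5h in library 5 (228).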

How the results depend on the processing

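Leaving out Controls 1 and 2 or the 3 mitochondria-rich libraries, the sex term and sample quality weights were tests chosen only after the result was seen. Of 197 calls of named genes, the fast muscle genes included, 197 held with DESeq2, 186 with limma-voom, 135 in batch 1 alone, 119 with library totals only and 82 without the 3 mitochondria-rich libraries, and 0 turned direction under any alternative. Of 115 list calls, 115 held with RLE factors, 104 without a batch term, 85 without Controls 1 and 2 and 72 in batch 1 alone. The replicate numbers did not pair the libraries: 0 of 16 same-numbered pairs had a correlation of deviations over 0.1 (-0.184 to 0.0894). With the replicate block 102 list calls and 156 named calls held. Depth outside mitochondrial transcripts limits Controls 1 and 2.

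Counts of genes changed that moved by over 1.5 times follow. With RLE factors counts were 0 for MEF2A against Control. With upper-quartile factors they were 0 for MEF2A against Control. With library totals only counts were 0 for MEF2A against Control, 412 for both viruses against Control and 1605 for YAP5SA against MEF2A. With no filter they were 358 for MEF2A against Control, 934 for both viruses against Control, 164 for both viruses against YAP5SA, 1103 for both viruses against MEF2A and 61 for the interaction. With the stricter filter counts were 0 for MEF2A against Control. With DESeq2 they were 2951 for YAP5SA against Control, 84 for MEF2A against Control, 814 for both viruses against Control, 18 for both viruses against YAP5SA, 1058 for both viruses against MEF2A and 22 for the interaction. With limma-voom counts were 0 for MEF2A against Control, 388 for both viruses against Control and 1 for both viruses against YAP5SA. With no batch term they were 0 for MEF2A against Control and 470 for both viruses against Control. With the replicate number as a block counts were 938 for YAP5SA against Control, 0 for MEF2A against Control, 207 for both viruses against MEF2A and 1573 for YAP5SA against MEF2A. With only the groups compared they were 702 for YAP5SA against Control, 1 for MEF2A against Control, 1091 for both viruses against Control, 4 for both viruses against YAP5SA and 2523 for both viruses against MEF2A. With batch 1 only counts were 482 for MEF2A against Control, 1395 for both viruses against Control, 6 for both viruses against YAP5SA, 667 for YAP5SA against MEF2A and 1 for the interaction. With batch 2 only they were 22 for MEF2A against Control. With the covariate for other cell types counts were 11 for MEF2A against Control, 664 for both viruses against Control, 879 for both viruses against MEF2A and 1729 for YAP5SA against MEF2A. With Controls 1 and 2 left out they were 138 for both viruses against Control and 644 for both viruses against MEF2A. With these and YAP5SA 3 left out counts were 75 for YAP5SA against Control, 1 for MEF2A against Control, 43 for both viruses against Control and 856 for YAP5SA against MEF2A. With a sex term they were 130 for both viruses against Control. With sample quality weights counts were 7 for MEF2A against Control, 864 for both viruses against Control, 55 for both viruses against YAP5SA, 4168 for both viruses against MEF2A and 5098 for YAP5SA against MEF2A. With a sex term and Controls 1 and 2 left out they were 834 for both viruses against MEF2A and 4021 for YAP5SA against MEF2A. Counts not given here were within 1.5 times or stayed at 0. Fewer libraries entered the tests of single batches, compared groups and left-out libraries. For the other settings the cause was not tested.

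A list is called reversed where its direction differed and it passed with either setting. This held for 77 of 5698 list values, and 358 more changed sign without passing in either. With library totals only lists turned, with medians in both viruses against MEF2A complex I (0.49) and complexes II to V (0.56). With batch 1 only lists turned, with medians in YAP5SA against Control matrix (-0.049), interferon (-3.33), MHC class I (-2.48), macrophage (-0.18) and ribosomal (-0.73), in MEF2A against Control fatty acid (0.62), interferon (-3.07) and macrophage (-1.02), in both viruses against Control macrophage (-0.75), in both viruses against YAP5SA complex I (0.22) and mitochondrially encoded (0.20) and in the interaction fatty acid (-0.45), matrix (0.12), interferon (4.27), MHC class I (2.79), endothelial (0.40), fibroblast (0.38), mural (-0.20), macrophage (0.50), mitochondrially encoded (3.21) and ribosomal (1.46). With the covariate for other cell types lists turned, with medians in YAP5SA against Control interferon (-1.59), MHC class I (-1.07) and ribosomal (-0.21), in both viruses against YAP5SA complex I (0.31), mitosis (0.058), MHC class I (0.96) and mitochondrially encoded (0.37), in YAP5SA against MEF2A MHC class I (-0.51) and in the interaction interferon (1.46), MHC class I (1.10), mitochondrially encoded (0.33) and ribosomal (0.55). With Controls 1 and 2 left out lists turned, with medians in YAP5SA against Control mitochondrially encoded (1.20), in MEF2A against Control complex I (0.089), complexes II to V (0.11), MHC class I (1.09), mitochondrially encoded (2.16) and ribosomal (0.10) and in both viruses against Control complexes II to V (0.21), mitochondrially encoded (0.74) and ribosomal (0.84). With these and YAP5SA 3 left out lists turned, with medians in YAP5SA against Control endothelial (0.038), in MEF2A against Control MHC class I (0.74), endothelial (0.18) and mitochondrially encoded (1.56), in both viruses against Control ribosomal (0.50) and in both viruses against YAP5SA complex I (0.22) and mitochondrially encoded (0.20). With a sex term lists turned, with medians in both viruses against YAP5SA complex I (0.24), mural (0.15) and mitochondrially encoded (0.40) and in the interaction mitosis (0.56) and ribosomal (0.50). With a sex term and Controls 1 and 2 left out lists turned, with medians in YAP5SA against Control mitochondrially encoded (1.77), in MEF2A against Control complex I (0.092), complexes II to V (0.15), matrix (0.18), MHC class I (1.30), mitochondrially encoded (2.31) and ribosomal (0.13), in both viruses against Control complexes II to V (0.21), mitochondrially encoded (0.83) and ribosomal (0.84) and in the interaction complexes II to V (-0.10), DNA replication (0.0082) and mitosis (-0.56). The cause was not tested.

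Leaving out 1 library at a time gave counts of 544 to 2998 for YAP5SA against Control, 0 to 101 for MEF2A against Control, 89 to 337 for both viruses against Control, 0 to 227 for both viruses against YAP5SA, 90 to 267 for both viruses against MEF2A, 841 to 3870 for YAP5SA against MEF2A and 0 to 11 for the interaction. Where a list turned, medians ran from -1.95 to 2.17 for MHC class I genes in YAP5SA against Control, -0.37 to 0.58 for ribosomal genes in YAP5SA against Control, -1.40 to 0.41 for MHC class I genes in MEF2A against Control, -0.68 to 1.13 for MHC class I genes in the interaction, -0.41 to 0.52 for ribosomal genes in the interaction, -0.24 to 0.22 for complex I genes in both viruses against YAP5SA, -0.49 to -0.013 for actin genes in both viruses against YAP5SA and -3.24 to 0.20 for mitochondrially encoded genes in both viruses against YAP5SA. Where an arm kept 1 library, it was assumed to vary like the other groups, and the cause was not tested. Batch 2 alone could not be run for comparisons with both viruses, which have no library there, nor the interaction with only the groups compared, which needs all groups.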

Other observations

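Of fast skeletal muscle genes, 6 chosen after their values were seen rose in YAP5SA, as did 1 of 10 abundant others. The tests of levels relative to Myh2, the one with Control subtracted last, and without 3 libraries were chosen only after the result was seen. Myh1, a fast myosin heavy chain, had 0 counts in all 5 Controls, a floor of 0.031 CPM for 3 counts over the group. It had 7.33 ± 1.9 CPM (mean ± SD, n = 3) in YAP5SA, at least 236-fold higher, and 38.1 ± 1.28 (n = 2) with both viruses, at least 1228-fold higher. In edgeR's test of YAP5SA against Control, Myh2 (6.65 ± 0.88, adjusted p = 0.00119), Myh8 (3.32 ± 0.33, adjusted p = 1.1e-05) and Mybph (6.04 ± 0.996, adjusted p = 0.00131), of the thick filament, rose. Cacna1s (4.60 ± 1.05, adjusted p = 0.0218) and Cdh15 (7.85 ± 0.94, adjusted p = 6.2e-05), a cadherin of muscle precursors, rose too. Myh1, Myh2 and Myh8 are close in sequence and can share reads, so their counts are uncertain. All 6 were called with both viruses as well, and 0 in MEF2A against Control, where edgeR called 3 genes in all. Cacna1s failed without YAP5SA 1 or 3 (adjusted p = 0.065 to 0.0926). Without the 3 mitochondria-rich libraries, only Myh8 of the 6 was called, in YAP5SA or with both viruses (in YAP5SA for Myh2 adjusted p = 0.238 at 7.42 on the log2 scale).

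Skeletal muscle tissue could bring these transcripts, and PCM1 also marks nuclei of its fibres, so the enrichment would not remove them. It would bring abundant fast-muscle transcripts too, of which 13 were listed, 7 of 10 tested over 1 CPM in Control and 1 also in another list. With both viruses their median level was 0.0133 of that of Myh2 (95% interval 0.00167 to 0.0423), with 11 of 13 below 0.1. In YAP5SA the median level was 0.0385 (0.00893 to 0.576), with 8 below 0.1. The median log2 fold change of the tested transcripts was 0.573 (-0.411 to 1.89). These intervals span the bounds of 0.1 and 1, but the heart's own transcripts count too. With Control subtracted, the median relative to Myh2 was 0.000423 (95% interval -0.00208 to 0.0393) in YAP5SA. With both viruses it was 0 (-0.00626 to 0.00372), the value of Tnnc2, 0 in both groups. Both are under the bound of 0.1, but without correction for transcript length. With both viruses, 12 of 13 were below 0.1, which argues against muscle as the whole source. As a part, or in YAP5SA (10 of 13, and Casq1 rose, 2.12 ± 0.36, adjusted p = 0.00184), muscle stays open. A response of cardiomyocytes was not tested and stays open.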
